A study of Mustela putorius furo with 9 samples.

How the data were processed

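RNA sequencing values from 9 libraries of NBL-7 cells were analysed, in 3 groups of 3. Groups were taken from the treatment label, and titles were kept in the group names because the title PBS1 and the label 500 µg/mL do not match in kind. The authors deposited 1 table of FPKM, fragments scaled to gene length and to library size, per the file headers, with 28494 genes. Columns for Ep1 and Ep2 carry the replicate numbers of the titles. The 3 PBS columns are named PBS1, PBS2 and PBS3, and only the stem PBS ties them to the group titled PBS1. They cannot be matched to single titles and are called here by their column names. Per the submitters' processing notes, Bowtie 0.12.2 and the genome build mm8 were used; mm8 is a mouse build, whereas the table names ferret genes on ferret scaffolds, so the build behind the values is not settled and no coordinates are printed. The counting tool, the annotation release, the strand setting and the treatment of reads shared between gene copies are not given in the sources used here. Values of genes with near-identical copies, which include many ribosomal protein genes, and of overlapping or antisense genes are therefore uncertain. Gene symbols were taken from the gene identifiers, since 25 entries of the name column had been turned into dates; 22335 of the 28494 identifiers had a symbol that was also present in a reference gene table of another assembly, used for names only.

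Depth was worked out from the deposited FPKM: in each library the value times the gene length was a whole multiple of 1 step for 100% of values above 0, within 0.02 of a whole number, which gives 12469849 to 13533480 fragments per library. Listed genes held between 98.9% and 99.9% of them. At this depth 1 fragment on a gene of 1000 bases equals between 0.0739 and 0.0802 FPKM, so differences between genes near the minimum of 1 FPKM rest on few fragments. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 2.73 to 10.9 over genes with at least 20 fragments in a pair, and no library was counted as a duplicate.

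The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, 1 mean per group, no block and all 9 libraries in 1 fit, so that the groups share an estimate of the spread. Genes with at least 1 FPKM in at least 3 libraries were tested, 11840 in all. Log2 differences and folds are on the log2(FPKM + 1) scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Gene lists, 30 in number, were fixed from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes. The 23 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, which passed 7, 5 and 10 lists for Ep2 minus Ep1, PBS1 minus Ep1 and PBS1 minus Ep2. Of the lists that camera called, 1 of 5, 2 of 6 and 2 of 2 passed fry as well; the cholesterol synthesis list passed fry for PBS1 minus Ep2 (adjusted p = 0.0127) but not for Ep2 minus Ep1 (0.0967) or PBS1 minus Ep1 (0.275). The fry test asks whether a list's genes move one way on balance and does not compare them with other genes.

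Named genes were the 10 genes with the largest differences in each direction that had a symbol, passed the threshold, reached a mean of 5 FPKM in a group and did not overlap between groups. Added to these were up to 4 called members per list (or up to 2 members with the highest values where none was called) and a fixed set of sterol, aryl hydrocarbon and oxidative stress genes. Some single genes that this rule names are not reported here; they stayed in the tests of all genes and of lists.

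The fit was tested on simulated fragments for the real genes, with 200 genes changed in Ep2. Over 11803 tested genes it recovered 65% of genes changed 1.5-fold and 91% of genes changed 2-fold for Ep2 minus Ep1, with 7 false calls among 168. For PBS1 minus Ep2 it recovered 67% and 88%, with 7 false calls among 167. For PBS1 minus Ep1, where nothing had been changed, it made 0 calls. The simulated noise was drawn independently for each gene and library, with no variation shared by the genes of a library. Sampling noise was also added to a spread that already held it. These rates therefore need not hold for the real libraries.

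Alternatives were other pseudocounts, other filters on low values, quantile normalization, equal library medians, no trend, sample weights, only the 6 libraries of a pair, the replicate number as a block, a required log2 difference of 1 and each library left out. Added after seeing the data were the removal of the trend on gene length, limma voom on the recovered fragments, and a fit without Ep1_1 and Ep2_1. GC content was not analysed here because it needs a genome sequence.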

Results

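The transcriptome of NBL-7 cells was measured by RNA sequencing in 9 libraries, after exposure to airborne particulate matter according to the study's title and design text. The labels call NBL-7 a ferret lung epithelial line; the name NBL-7 is also in use for a mink lung epithelial line, and the species was not tested here. The libraries form 3 groups of 3. Those titled Ep1 are labelled untreated, those titled Ep2 are labelled 250 µg/mL, and those titled PBS1 are labelled 500 µg/mL. PBS is the usual name of a buffer given as a vehicle, so the title and the treatment label of the PBS1 group point to different treatments; all 3 pairs of groups were therefore compared, and groups are named by title with the label beside it. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The libraries held between 12469849 and 13533480 fragments, as worked out from the deposited values.

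The cholesterol synthesis gene MVD averaged 99.8 FPKM in PBS1, 67.9 FPKM in Ep1 and 39.0 FPKM in Ep2, and the S-phase cyclin gene CCNE2 averaged 9.37, 9.17 and 15.2 FPKM. Over the 3 groups, 5372 of 11840 tested genes passed the limma F-test at an adjusted p of 0.05. The first principal component held 57.1% of the variance and placed the PBS1 libraries between -19.3 and -15.3, the Ep1 libraries between -14.7 and 2.89 and the Ep2 libraries between 15.3 and 24.7. Library Ep1_1, at -14.7, lay next to the PBS1 libraries, whereas Ep1_2 and Ep1_3 lay at -0.37 and 2.89; Ep2_1 was the Ep2 library nearest to Ep1. Across genes, the correlation of log2 values between libraries was 0.972 to 0.984 between PBS1 and Ep2, 0.975 to 0.992 between Ep1 and Ep2, and 0.986 to 0.994 between PBS1 and Ep1. Within groups it was 0.994 to 0.995 for PBS1, 0.990 to 0.994 for Ep1 and 0.991 to 0.994 for Ep2. Ep1_1 correlated at 0.992, 0.993 and 0.994 with columns PBS1, PBS2 and PBS3, but at 0.991 with Ep1_2 and 0.990 with Ep1_3. The Ep1 means therefore average libraries that were not alike. Without Ep2_3, 3504 genes passed the F-test.

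**Figure D1:**
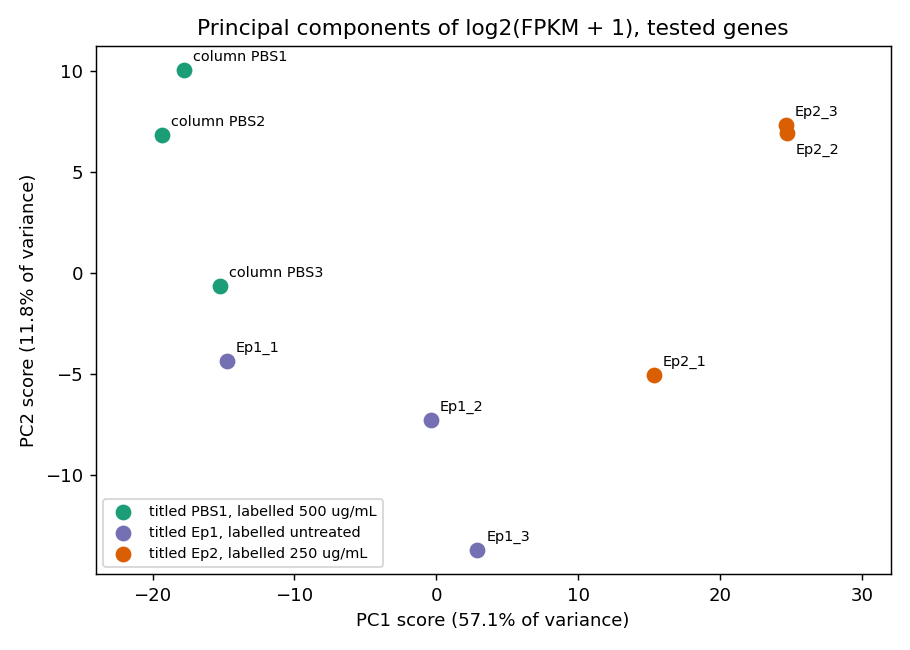
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 1), with 1 point per library coloured by group and the share of variance on each axis (57.1% and 11.8%). The PBS1 libraries and Ep1_1 lie at the left, between -19.3 and -14.7, and the Ep2 libraries lie at the right, between 15.3 and 24.7.

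The first comparison, between the groups labelled 250 µg/mL and untreated, asks how the transcriptome differs at the lower labelled dose. Of the cholesterol synthesis genes called lower in Ep2, MVD, which makes isopentenyl diphosphate, measured 39.0 ± 9.81 FPKM (SD, n = 3) in Ep2 and 67.9 ± 8.17 FPKM (n = 3) in Ep1, a log2 difference of -0.81 (SE 0.14, adjusted p = 0.00543). MVK, the mevalonate kinase, differed by -0.76 (SE 0.14), and LSS, which closes the sterol rings, by -0.70 (SE 0.13). FASN, the fatty acid synthase, measured 255 ± 91.8 FPKM in Ep2 against 478 ± 51.2 FPKM in Ep1, and ACLY, which supplies cytosolic acetyl-CoA, 253 ± 52.0 FPKM against 393 ± 35.7 FPKM. CCNE2, a cyclin of S-phase entry, was higher in Ep2, at 15.2 ± 2.12 FPKM against 9.17 ± 0.823 FPKM (log2 difference 0.67, SE 0.10).

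Of the 17 measured cholesterol synthesis genes, 6 fell in Ep2, 0 rose and 11 did not pass the test over all genes; 10 passed when adjusted over the list alone. The median log2 difference was -0.43 (camera adjusted p = 0.000571), a call lost with an estimated correlation between genes in place of the preset one (adjusted p = 0.673). The study's title names cholesterol metabolism, so this list is not independent evidence of its direction. HMGCS1, which makes HMG-CoA, was not called (99.1 ± 42.4 FPKM in Ep2, 147 ± 22.3 FPKM in Ep1, adjusted p = 0.0647, and 0.00258 without Ep2_1), nor was SQLE, the squalene epoxidase (adjusted p = 0.457, and 0.0436 without Ep2_1). Of 16 sterol sensing and uptake genes, 4 fell and 0 rose (9 adjusted over the list alone; median -0.18, camera adjusted p = 0.0145, and adjusted p = 0.673 with an estimated correlation), among them SREBF1, at 24.0 ± 3.26 FPKM against 36.2 ± 1.43 FPKM. Of 13 fatty acid synthesis genes, 5 fell and 0 rose (6 adjusted over the list alone; median -0.22, adjusted p = 0.0324, and adjusted p = 0.679 with an estimated correlation). Of 19 integrated stress response genes, 7 fell and 0 rose (9 adjusted over the list alone; median -0.19, adjusted p = 0.0468, and adjusted p = 0.673 with an estimated correlation), among them the transcription factor CEBPB, with 28.5 ± 7.76 FPKM against 54.4 ± 6.82 FPKM. Of 26 DNA replication genes, 9 rose and 0 fell (9 adjusted over the list alone; median 0.09, adjusted p = 0.0145, and adjusted p = 0.673 with an estimated correlation); CDC6, which loads the replicative helicase, measured 12.3 ± 1.65 FPKM against 8.30 ± 0.927 FPKM.

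Genes outside those 5 lists were called as well. The chaperone HSPA8 rose to 1358 ± 142 FPKM in Ep2 from 969 ± 70.0 FPKM, while the small heat shock gene HSPB1 measured 370 ± 77.6 FPKM against 529 ± 33.9 FPKM. The mitotic kinase TTK measured 24.1 ± 1.21 FPKM against 16.3 ± 2.89 FPKM. The apoptosis genes BBC3 and BAX were lower, with log2 differences of -0.96 (SE 0.20) and -0.54 (SE 0.09). Of the 21 tested genes of their p53 and apoptosis list, 6 were called lower and 2 higher, and the list did not pass (camera adjusted p = 0.191). NKX2-1, a lung epithelial transcription factor, measured 9.35 ± 1.71 FPKM in Ep2 and 14.4 ± 1.37 FPKM in Ep1. The 2 mitochondrial ribosomal RNAs, l-rRNA and s-rRNA, were higher in Ep2 with log2 differences of 0.95 (SE 0.15) and 0.82 (SE 0.18). How far these values reflect mitochondrial expression is uncertain, since 12 of 13 listed mitochondrially encoded protein genes were at 0 in all libraries. Among the genes with the largest decreases were MRPS15 (-1.38, SE 0.21), TMEM256 (-1.16, SE 0.24) and OST4 (-0.97, SE 0.18). The size of these decreases depends on which Ep1 library is used. In Ep1_1, Ep1_2 and Ep1_3, MRPS15 measured 14.7, 24.7 and 29.0 FPKM and TMEM256 25.3, 14.2 and 12.9 FPKM. OST4 measured 181, 116 and 102 FPKM in the same libraries. Each of the calls held with any 1 library left out.

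In all, 3240 genes, 27.4% of those tested, passed an adjusted p of 0.05, 1586 higher and 1654 lower in Ep2. Their median fold was 1.26, and 37 had an absolute log2 difference of at least 1, 5 higher and 32 lower in Ep2. Genes of at most 1000 bases made up 29 of these 37 and 12.9% of the tested genes. The count was 1839 without Ep1_1, 1499 without Ep2_2 and 1258 without Ep2_3, the number of called lists was 3 without Ep1_3, Ep2_2 or Ep2_3, and the cholesterol median was -0.24 without Ep2_2. The median and the mean of the interferon response list (0.05 and -0.07) and of the unfolded protein response list (-0.02 and 0.01) differed in sign.

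**Figure D2:**
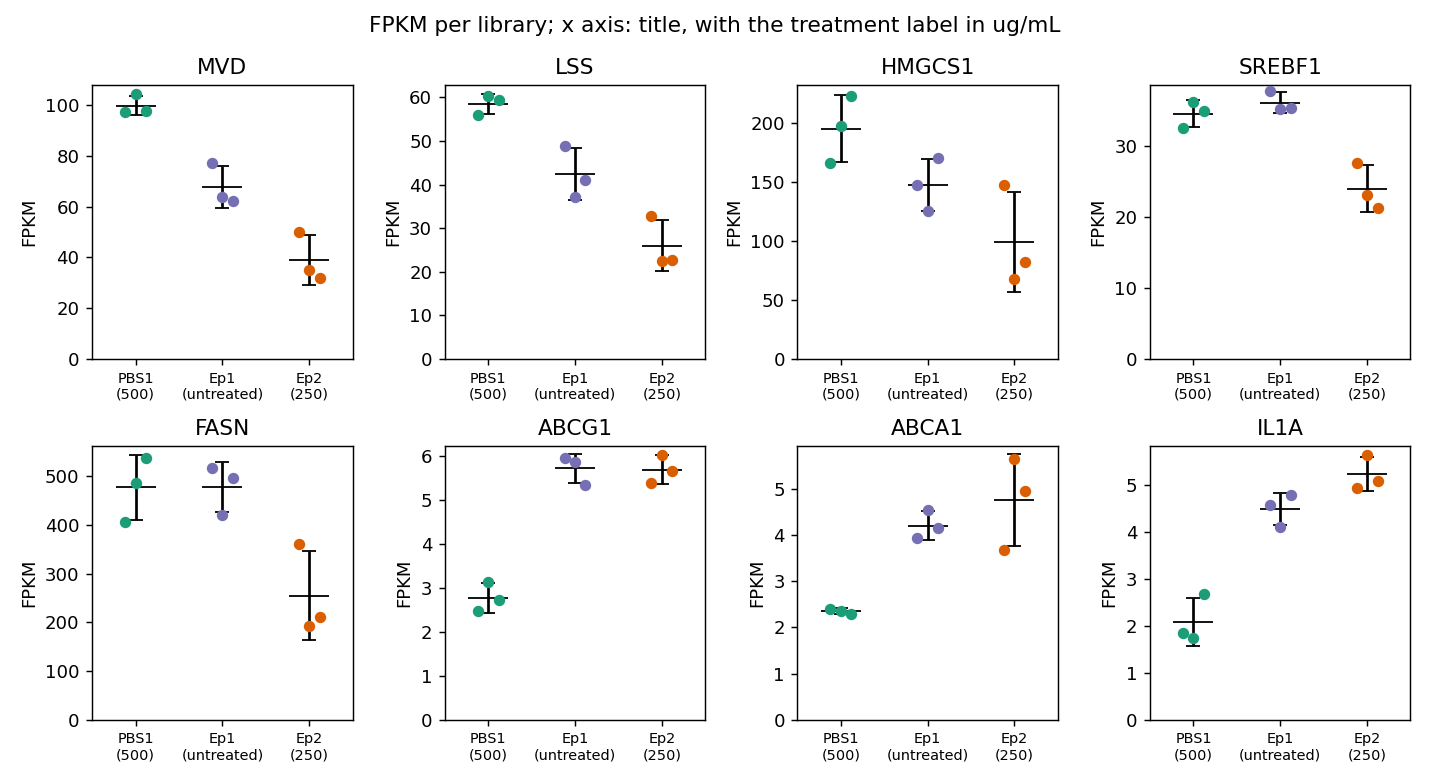
FPKM of 8 genes in each library by group, with points for libraries and bars for the mean ± SD of 3 libraries; every vertical axis starts at 0. MVD averages 99.8, 67.9 and 39.0 FPKM in PBS1, Ep1 and Ep2, whereas ABCG1 averages 2.77, 5.72 and 5.69 FPKM.

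The second comparison set the group labelled 500 µg/mL, titled PBS1, against the group labelled untreated, titled Ep1. ABCG1, a cholesterol exporter, measured 2.77 ± 0.341 FPKM (SD, n = 3) in PBS1 and 5.72 ± 0.330 FPKM (n = 3) in Ep1, a log2 difference of -0.84 (SE 0.09, adjusted p = 0.00646). The inflammatory cytokine gene IL1A was also lower in PBS1, at 2.09 ± 0.513 FPKM against 4.49 ± 0.348 FPKM (log2 difference -0.84, SE 0.12, adjusted p = 0.0257), as was MDM2, the ligase that degrades p53, at 74.9 ± 6.17 FPKM against 101 ± 3.25 FPKM. GPX1, a glutathione peroxidase, was higher in PBS1, at 1415 ± 69.9 FPKM against 919 ± 55.0 FPKM (log2 difference 0.62, SE 0.07, adjusted p = 0.00851). ANGPTL2, a secreted angiopoietin-like protein, differed by 0.70 (SE 0.07, adjusted p = 0.00646), and the carbonic anhydrase gene CA9, a hypoxia target, by 0.45 (SE 0.07, adjusted p = 0.0411). Each of these 6 calls was lost without Ep1_2; that of GPX1 also without Ep1_3, and those of IL1A, CA9 and MDM2 also without Ep1_3, column PBS1, column PBS2 or Ep2_3, and for MDM2 Ep2_2. All 6 were also lost with no filter on low values, CA9 with quantile normalization, CA9 and MDM2 without the intensity trend, and IL1A and MDM2 with only the 6 libraries compared.

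Single members of the sterol lists mostly did not pass. Of the 9 tested cholesterol efflux genes, 1 was called, lower in PBS1, and 7 had a log2 difference below 0. Their median was only -0.04 (camera adjusted p = 0.0545, fry adjusted p = 0.0198). ABCA1, another cholesterol exporter, measured 2.35 ± 0.0596 FPKM in PBS1 and 4.20 ± 0.317 FPKM in Ep1 (adjusted p = 0.0606, and 0.0144 without Ep1_1 or 0.0291 without Ep2_1), and TIPARP, a target of the aryl hydrocarbon receptor, 60.9 ± 4.82 FPKM and 79.9 ± 7.23 FPKM (adjusted p = 0.0634, and 0.00593 without Ep1_1). Of the 17 cholesterol synthesis genes, 0 were called over all genes and 5 when adjusted over the list alone, a list the title names and so not independent evidence; their median log2 difference was 0.31 (camera adjusted p = 0.000356, and adjusted p = 0.594 with an estimated correlation), with 16 of 17 above 0. The HMGCS1 log2 difference was 0.40 (SE 0.23) and that of SQLE 0.23 (SE 0.11). The DNA replication list (median 0.09, camera adjusted p = 0.0145), the unfolded protein response list (0.08, adjusted p = 0.0238) and the hypoxia and glycolysis list (0.13, adjusted p = 0.0343) passed on the side of PBS1, with 0 of 26, 1 of 18 and 1 of 19 members called; adjusted over the list alone these were 3, 7 and 2. Their adjusted p was 0.614, 0.309 and 0.586 with an estimated correlation. The inflammatory cytokine list (-0.15, adjusted p = 0.0242) and the p53 and apoptosis list (-0.13, adjusted p = 0.0238) passed on the side of Ep1, with IL1A and MDM2 as their called members and 1 of 7 and 2 of 21 passing when adjusted over the list alone. Their adjusted p was 0.309 and 0.586 with an estimated correlation.

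In all, 17 genes passed, 9 higher and 8 lower in PBS1, and 2648 genes had an unadjusted p under 0.05. This count moved with the fit, to 0 with no filter on low values, 79 at a minimum of 5 FPKM, 11 without the trend, 39 with the gene length trend removed, 547 with voom and 3593 with sample weights. It also moved with the libraries: it was 0 without Ep1_2, 3 without Ep1_3, 8 without column PBS1, 9 without column PBS2, 47 without column PBS3, 27 without Ep2_1, 8 without Ep2_3 and 1887 without Ep1_1, the Ep1 library nearest to PBS1, and the number of called lists was 2 without Ep1_1 and 9 without Ep1_3. The median and the mean of the metal response list (-0.04 and 0.04) and of the matrix list (-0.03 and 0.01) differed in sign.

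The third comparison, between the groups labelled 500 and 250 µg/mL, showed the widest differences. MVD measured 99.8 ± 3.84 FPKM (SD, n = 3) in PBS1 and 39.0 ± 9.81 FPKM (n = 3) in Ep2, a log2 difference of 1.36 (SE 0.14, adjusted p = 0.000298), LSS differed by 1.16 (SE 0.13), and HMGCS1 measured 195 ± 28.6 FPKM against 99.1 ± 42.4 FPKM (1.04, SE 0.23, adjusted p = 0.00453). FASN (0.95, SE 0.20) was higher in PBS1 as well. The exporters ABCG1 (-0.83, SE 0.09) and ABCA1 (-0.77, SE 0.12) were lower in PBS1, as were IL1A (-1.02, SE 0.12), TIPARP (-0.49, SE 0.08) and the p53 ligase gene MDM2 (-0.57, SE 0.07). Among the largest differences were those of PFDN6 and PFDN2, subunits of the prefoldin chaperone, at 1.97 (SE 0.24) and 1.54 (SE 0.17), and of the ribosomal protein genes RPL11 and RPS14, at 1.51 (SE 0.17) and 1.35 (SE 0.16). The mitochondrial l-rRNA, with the limit given above, was lower in PBS1, at 8.69 ± 0.522 FPKM against 23.5 ± 5.75 FPKM. The mitochondrial ribosomal protein gene MRPL20 was lower too, at 24.7 ± 2.40 FPKM against 60.9 ± 10.8 FPKM.

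Of the 17 cholesterol synthesis genes, 15 were higher in PBS1, 0 lower and 2 not called (15 adjusted over the list alone, not independent evidence given the title; median 0.65, camera adjusted p = 2.82e-05). Of 16 sterol sensing and uptake genes, 8 were higher and 1 lower (9 adjusted over the list alone; median 0.26, adjusted p = 0.0428). Both calls were lost with an estimated correlation (adjusted p = 0.814 for each). The other 21 tested lists did not pass camera, and 8 of them passed fry. Over all 11840 tested genes 49.6% were called, 3013 higher and 2862 lower in PBS1, so list counts near that share show nothing particular to a list. Higher and lower called members were 7 and 0 of 13 for fatty acid synthesis, 2 and 3 of 9 for cholesterol efflux, 4 and 4 of 16 for fatty acid oxidation, 8 and 1 of 16 for targets of NRF2, 0 and 3 of 6 for metal response, and 0 and 1 of 7 for inflammatory cytokines. They were 1 and 4 of 11 for interferon response, 8 and 4 of 18 for unfolded protein response, 9 and 2 of 19 for integrated stress response, 4 and 4 of 12 for heat shock, 7 and 6 of 21 for p53 and apoptosis, 5 and 12 of 23 for mitosis, and 3 and 8 of 26 for DNA replication. For hypoxia and glycolysis they were 10 and 3 of 19, for lysosome 9 and 7 of 22, for autophagy 4 and 4 of 18, for immediate early genes 8 and 3 of 21, for matrix genes 9 and 4 of 22, for epithelial junctions 5 and 1 of 15, for oxidative phosphorylation 7 and 5 of 21, and for ribosomal proteins 19 and 8 of 45. Median and mean differed in sign for interferon response (-0.19 and 0.02), heat shock (-0.05 and 0.0002), p53 and apoptosis (-0.04 and 0.03) and DNA replication (0.02 and -0.02), and the test of fatty acid oxidation pointed down at a median of 0.04.

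The remaining 7 lists had fewer than 5 tested members. Of the 3 tested targets and partners of the aryl hydrocarbon receptor, TIPARP, NFE2L2 and AHR, all were called lower in PBS1 than in Ep2, at 60.9, 58.8 and 13.6 FPKM against 85.8, 83.1 and 16.8 FPKM, and the AHR call was lost without column PBS1, column PBS2 or Ep2_2. CYP1A1 and CYP1B1 were not analysed here. Of 2 airway and alveolar markers, NKX2-1 was called higher in PBS1 (14.9 ± 0.359 FPKM against 9.35 ± 1.71 FPKM). Tested markers of other cell types were not called in this comparison: the fibroblast genes PDGFRA and COL1A2 measured 1.10 and 1.75 FPKM in PBS1 and 1.53 and 1.23 FPKM in Ep2, and the leukocyte gene TYROBP 1.36 and 1.37 FPKM. The endothelial gene TEK measured 16.6 FPKM in PBS1, 15.2 FPKM in Ep2 and 12.5 FPKM in Ep1; it was called only between Ep2 and Ep1 (adjusted p = 0.0245), and not without Ep1_1, Ep1_3, Ep2_2 or Ep2_3. Of 2 histone genes, H3F3B was called at -0.19 (SE 0.07), a call lost without any one of 7 libraries. Of 13 listed mitochondrially encoded protein genes, 12 were listed at 0 in all libraries and 0 were tested.

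In all, 5875 genes passed, 3013 higher and 2862 lower in PBS1; their median fold was 1.30, and 158 had an absolute log2 difference of at least 1, 131 of them higher in PBS1. Genes of at most 1000 bases made up 109 of these 158 and 12.9% of the tested genes. The number of called lists was 1 without column PBS3, Ep1_1, Ep1_3, Ep2_2 or Ep2_3 and 3 without Ep2_1.

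**Figure D3:**
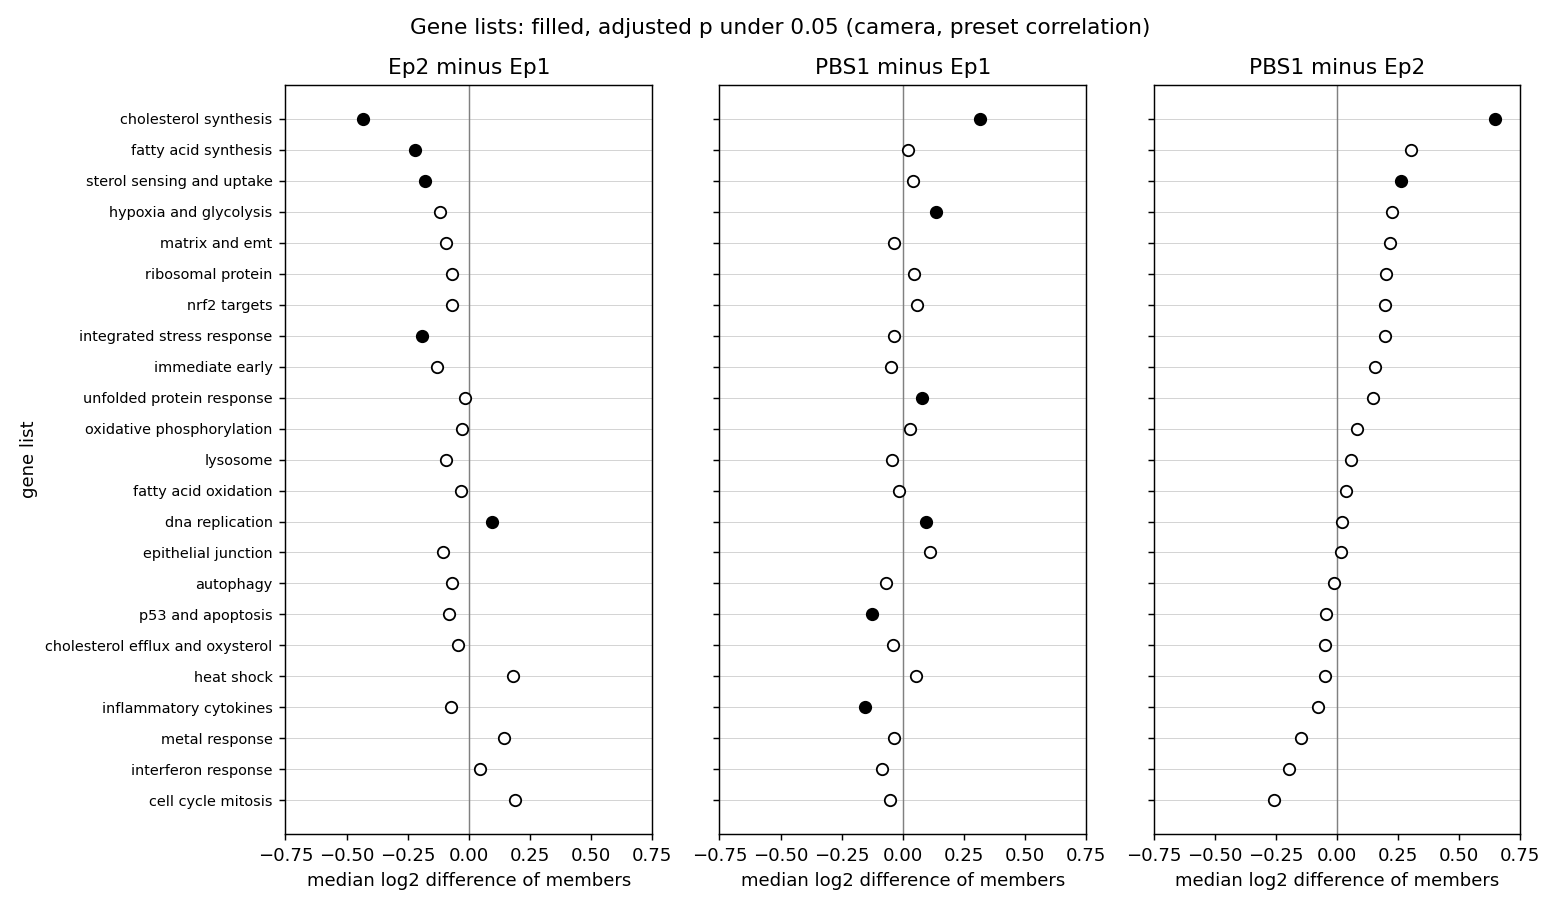
Median log2 difference of the tested members of 23 gene lists (rows) in the 3 comparisons (panels), with filled points where camera with a preset correlation gave an adjusted p under 0.05; 0 lists passed with an estimated correlation. Cholesterol synthesis lies at -0.43, 0.31 and 0.65.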

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

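The fits with the gene length trend removed, with voom and without both Ep1_1 and Ep2_1 were chosen after the data were seen; leaving out that pair, the library of each Ep group nearest to PBS1, is a choice that widens the gap to PBS1. The gene counts for Ep2 minus Ep1, PBS1 minus Ep2 and the 3 groups together stayed within 1.5 times under every alternative with all libraries of the groups compared, except where a log2 difference of at least 1 was required as well, which left 37, 158 and 157 genes, and 1 for PBS1 minus Ep1. The 17 genes of PBS1 minus Ep1 became 0 with no filter on low values (limma, 19299 genes tested), 79 at a minimum of 5 FPKM, 11 without the trend, 3593 with sample weights, 39 with the length trend removed, 547 with voom and 2294 without Ep1_1 and Ep2_1. With 1 library left out, counts ranged from 1258 to 3417 for Ep2 minus Ep1, from 0 to 1887 for PBS1 minus Ep1, from 4498 to 6237 for PBS1 minus Ep2 and from 3504 to 5809 over the 3 groups. The called lists, in the order Ep2 minus Ep1, PBS1 minus Ep1 and PBS1 minus Ep2, were 5, 6 and 2, and 0 in each with an estimated correlation; leaving out 1 library gave 3 to 5, 2 to 9 and 1 to 3. For PBS1 minus Ep1 they were 3 with quantile normalization, 3 with sample weights and 3 without Ep1_1 and Ep2_1; for PBS1 minus Ep2 they were 1 with quantile normalization, 1 without the trend, 1 with only the 6 libraries compared and 5 without Ep1_1 and Ep2_1. The cholesterol synthesis medians of -0.43, 0.31 and 0.65 did not pass with an estimated correlation (adjusted p = 0.673, 0.594 and 0.814), and with 1 library left out they ranged from -0.55 to -0.24, 0.24 to 0.37 and 0.50 to 0.87. Of 5028 combinations of a single gene's result and an alternative, 4621 kept direction and side of the threshold, 366 lost and 37 gained a call, and 4 changed sign, 0 of them among called genes: INSIG1 in PBS1 minus Ep1 (-0.0278 with quantile normalization, -0.0282 without column PBS3 and -0.0279 without Ep1_2, up to 0.102 without Ep1_3) and SQLE in Ep2 minus Ep1 (0.0162 without Ep2_2, against -0.256 without Ep2_1 and -0.28 without Ep1_1 and Ep2_1). A block on the replicate number was possible for Ep2 minus Ep1 alone, because the PBS columns carry no title number. With it 2974 genes passed, against 2342 in the same 6 libraries without it. Deviations of same-numbered libraries correlated at 0.152, 0.072 and 0.065. Ep1_1 and Ep1_3 matched the Ep2 library of their own number best, whereas Ep1_2 matched Ep2_3. The main fit had no block because no protocol names a pairing, and whether the numbers mark pairs is not settled. For a table of read counts, an edgeR quasi-likelihood test had been planned as the main test, with a DESeq2 alternative. Neither was run on this table of FPKM. Instead, voom was run on the fragments worked out from it. The cause of these shifts was not tested; depth limits genes near 1 FPKM.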

Other observations

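The tests of gene families, of dose order, of gene length and depth, of matched random lists and of single libraries were chosen after the results were seen. Among 16 families of genes with shared symbols, 48 tests in all, translation initiation factor genes rose in Ep2 against Ep1 in 14 of 48 members and fell in 1 (median log2 difference 0.09, camera adjusted p = 0.0331; adjusted p = 0.474 with an estimated correlation). Centromere protein genes, which build the kinetochore, rose in 7 of 18 members and fell in 1 (median 0.25, adjusted p = 0.0240; adjusted p = 0.474 with an estimated correlation). Collagen genes, of the extracellular matrix, fell in 6 of 13 members and rose in 0 (median -0.21, adjusted p = 0.0240; adjusted p = 0.474 with an estimated correlation), and 6 were higher in PBS1 than in Ep2 (median 0.29, adjusted p = 0.0261; adjusted p = 0.599 with an estimated correlation). Ubiquitin-specific protease genes, which remove ubiquitin, were lower in PBS1 than in Ep2 in 18 of 46 members and higher in 4 (median -0.17, adjusted p = 0.00693; adjusted p = 0.599 with an estimated correlation). Between PBS1 and Ep1, 4 families passed with at most 1 called member each: ubiquitin-specific proteases (median -0.09, adjusted p = 0.00538), RNA polymerase subunits (0.09, adjusted p = 0.0102), mitochondrial ribosomal proteins (0.10, adjusted p = 0.0186) and proteasome subunits (0.06, adjusted p = 0.0239). With an estimated correlation their adjusted p was 0.611, 0.354, 0.611 and 0.685. Differences of PBS1 from Ep1 tended to fall with gene length (Spearman correlation -0.23 over the tested genes). The families were not refitted with that trend removed, so gene length stays open for these 4. The proteasome median turned to -0.0043 with quantile normalization; the other medians given here kept their sign with it, and all did with equal library medians.

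The differences of Ep2 from Ep1 and of PBS1 from Ep1 share the Ep1 libraries and tended to run in opposite directions across genes, with r = -0.23 and a covariance of -0.012. Simulated unchanged groups that share a simulated group gave means of 0.50 and 0.0081 over 20 runs. All libraries were simulated there, with each gene drawn independently. Variation that genes of a library share is left out, so the simulated values do not show what unchanged real groups would give. Genes are not independent replicates. Against Ep2, the differences of Ep1 and PBS1 had r = 0.86 (simulated 0.49) and a covariance of 0.082 (simulated 0.0079). Of their calls, 1463 were higher in both (421 for independent lists), 1402 lower in both (383 for independent lists) and 1 went opposite ways. Part of the excess may come from the shared controls, since 3 libraries cannot be split into 2 sets of at least 2. The Ep2 mean lay between the means of the other groups for 4.75% of the genes called over the 3 groups.

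For each pair of groups 1 of the 10 splits of its 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05; the real counts were 3240, 17 and 5875 and the highest other count was 0 in each. Over the 3 groups, 1 of 100 splits, the real one, gave as many genes as the real 5372, so a random assignment of these libraries would rarely give that count. Those 100 are a sample of the possible splits. The test does not tell PBS1 from Ep1, and it cannot show that the libraries of a group came from separate cultures. The highest other split gave 5013 genes. It exchanged column PBS3 with Ep1_1 and left the Ep2 libraries together, as did the next highest, with 2781 and 2734 genes. The count thus depends largely on keeping the Ep2 libraries together. That does not make Ep2 a set apart from the other 6 libraries: Ep1_3 correlated at 0.992 with Ep2_1 but at 0.990 with Ep1_1.

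The titles and the treatment labels disagree on which group was exposed. A response that grows with the labelled dose would put Ep2 between the others. The mean of Ep2 lay in the middle for 4.75% of the genes called over the 3 groups (2.30% to 11.5% with 1 library left out), against 78.8% for Ep1. The group means thus argue against that order for most of these genes. Genes vary together and are not independent here, since the first principal component alone held 57.1% of the variance. A difference between library batches, which the labels do not give, could also set the order of the means. If the PBS1 libraries were unexposed, targets of the aryl hydrocarbon receptor could be higher in both Ep groups; the median log2 difference from PBS1 of the list was 0.31 for Ep1 and 0.49 for Ep2, but it rests on TIPARP, NFE2L2 and the receptor gene AHR, whose own value is the 0.31, with 0 CYP1 genes among them. The 2 readings of the labels therefore cannot be told apart by these genes. That the labels are right and the response is not ordered by dose stays open too, as untested.

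Many small differences were called between Ep2 and the other groups. A trend on gene length is argued against as the whole cause of the gene count, since 5911 genes passed for PBS1 minus Ep2 once it was removed, against 5875 before. Removing a trend does not remove a wider scatter of short genes in both directions. The SD of their log2 differences was 0.54 for genes of at most 1000 bases and 0.32 for longer ones. Short genes made up 109 of the 158 differences of at least 1, and a length effect on those was not tested. Depth is argued against as well: mean fragments of PBS1 and Ep2 differed by 0.350%, the smallest gap of the 3 pairs, the others being 2.82% and 3.16%. GC content was not tested and may contribute, as may a difference between library batches, which the labels do not give, and the exposure itself.

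Of 17 cholesterol synthesis genes, 15 were called lower in Ep2 than in PBS1 and 6 lower than in Ep1. A shift shared by genes of like expression and length is argued against as the whole cause. The list median for PBS1 minus Ep2, 0.65, lay at percentile 100 of 10000 random lists matched on both, whose highest was 0.38. The list medians for PBS1 minus Ep1 (0.31) and Ep2 minus Ep1 (-0.43) lay at percentiles 100 and 0. Part of the 0.65 is therefore PBS1 lying above Ep1. The random lists draw genes separately, whereas the estimated correlation between genes of the cholesterol list was 0.707. At that correlation its call was lost (camera adjusted p = 0.814, and 0.673 for Ep2 minus Ep1), so variation between libraries that these genes share stays open. That 1 library carries the difference is argued against by the lowest median with 1 library left out, 0.50 for PBS1 minus Ep2. Against Ep1 the median moved from -0.43 to -0.24 without Ep2_2, still past the threshold (camera adjusted p = 0.0183). Leaving out 1 library cannot show whether Ep2_2 and Ep2_3 carry most of the shift. Without Ep2_1 the medians were 0.87 for PBS1 minus Ep2 and -0.55 for Ep2 minus Ep1. In Ep2_1, HMGCS1 (147 FPKM) and SQLE (200 FPKM) were not below their Ep1 means of 147 and 179 FPKM. MVD (50.1 FPKM) and LSS (32.7 FPKM) were below theirs, 67.9 and 42.4 FPKM. An effect of the exposure on sterol synthesis is a candidate explanation, but which group was exposed is unsettled, and GC content and differences between cultures in density or medium were not tested.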
